A study of Homo sapiens with 6 samples.

How the data were processed

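RNA was measured by sequencing in Kasumi-1 cells, a human acute myeloid leukemia line that carries the AML1-ETO fusion. The cells had been infected for 4 days with a virus expressing a control shRNA, JMJD1C shRNA63 or JMJD1C shRNA95, and 2 libraries were made for each of these 3 groups. Groups were taken from the titles of the samples. Nothing in the labels states that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

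The submitters' processing notes name TopHat2 2.0.8b and Cuffdiff 2.1.1 and the genome build hg19, with no role or order. Whether the library preparation kept the strand is not given in the sources used here. There were 3 tables of 62016 Ensembl genes each, with the columns of a Cuffdiff gene comparison per the file headers. Each of the 2 JMJD1C tables holds 1 FPKM value per group, into which the authors combined the 2 libraries of the group. FPKM is the number of fragments scaled to transcript length and to the mapped fragments of the library, and the authors scaled it within each table: the control FPKM of the shRNA63 table was 1.03 times that of the shRNA95 table at the median. Levels were therefore compared only within a table. Each table also holds the authors' log2 fold change, their test statistic (a score per gene), and a p-value with its adjusted q-value, all as deposited. The third table compares 1 library of cells with an AML1-ETO shRNA and 1 control library, both from another published series, per the design text. Its 2 columns of FPKM belong to libraries of another series and were not used. Only the comparison columns of that table were used, and each sentence with a value from it names the authors' deposited table. This comparison has no replicate check, and its test compares those 2 libraries, not the conditions.

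A gene was called changed where the authors' q-value, as deposited, was under 0.05 and the gene had passed their filter for testing. No test across libraries could be made here, because the tables hold no value per library. The error given with a log2 fold change is the size of the authors' log2 fold change divided by their test statistic. The deposited p-values are smaller than a normal distribution gives for that statistic. In both JMJD1C tables the normal deviate of p was 1.42 times the statistic at the median, and in the AML1-ETO table it was 1.04 times, so the errors given for JMJD1C are the wider of the 2 readings. An alternative with errors scaled to the deposited p was added after this had been seen. The smallest deposited p was 5e-05 in each table, which gives the many genes at that limit the same q. For medians, correlations and rankings, a ratio was computed from the authors' FPKM as log2((FPKM + 1)/(FPKM + 1)), over tested genes with an FPKM of at least 1 in the higher group. This ratio understates the change of genes with low values. For the AML1-ETO table the authors' log2 fold change took its place, which departs from the plan made before the data were examined. Correlations, shares of equal sign, named genes and the alternatives on level used the FPKM of the JMJD1C tables as the filter for it. The gene lists had no filter on level in that table: all 21727 tested genes with a finite log2 fold change in the authors' deposited table entered, so the members of a list differ between tables.

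Read counts were not used here, so the depth of each library is unknown. Relative depth was read from genes with very low values. The most frequent log2 fold change of untested genes with values in both groups was 0.34 in the shRNA63 table and 0.50 in the shRNA95 table, shared by 154 and 156 genes. If these are genes with equal reads in both groups, 1 read was worth 1.27 and 1.41 times as much as in the controls, and the depth of the shRNA groups was 0.79 and 0.71 times that of the control group. The median error of a log2 fold change in the shRNA63 table was 0.58 for genes with 1 to 5 FPKM, 0.38 for 5 to 20 FPKM, 0.34 for 20 to 100 FPKM and 0.29 above that.

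The difference between hairpins was tested per gene as the difference of the authors' log2 fold changes over the root of their summed squared errors, two-sided against a normal distribution, with Benjamini-Hochberg adjustment. No exact test can be made from group values, so these p-values rest on that approximation and on errors from 2 libraries per group. Errors below the 10th percentile were raised to it, a step added after implausibly small errors had been seen. The control libraries are shared, so independent errors are too wide here and the test is conservative. It was tested on simulated data for 13870 genes with 200 changed: it recovered 1.5% of them at a log2 difference of 1, 47.5% at 2 and 69% at 3, with 0, 8 and 5 false calls. Overlaps of calls between hairpins were compared with the product of the separate counts over the number of genes tested in both. The effect of shared controls was simulated 100 times per setting, with unchanged groups and errors from either the statistic or the p-value. It was first run over all 13870 genes, with errors above the 99th percentile lowered to it, where the simulated covariance exceeded the observed one. After that result had been seen, limits of 0.5 and 0.3 on the errors scaled to the deposited p and floors of 1, 5 and 20 FPKM were tried, which gave 18 settings in all. The difference of observed and simulated covariance was above 0 in 12 of the 18, namely in 0 of 6 without a limit on the errors (from -0.567 to -0.0462), in 6 of 6 with errors under 0.5 (from 0.00696 to 0.0396) and in 6 of 6 with errors under 0.3 (from 0.0274 to 0.0523).

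Before the data were examined, 31 gene lists were fixed, drawn up from general knowledge of the field and not from these tables. They hold 694 genes, of which 689 had a row and 26 stood in more than 1 list. The lists of genes known as repressed by AML1-ETO and of neutrophil granule genes share 4 genes. For each list the called members were counted over all genes tested and adjusted over the list alone. The called members were also compared with other measured genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over all lists and tables. The list median was placed among 10000 random lists matched on expression in 20 bins. Random lists draw genes singly, while members of a list can move together. These percentiles and the Fisher p-values treat genes as independent and do not measure spread between cultures. Under the alternatives a median counted as apart from random lists when it lay in the outermost 0.5% at either end, a definition chosen after the data were seen. The lists covered H3K9 demethylases, the AML1-ETO complex, stem cell genes, targets of AML1-ETO, blood lineages, the cell cycle, p53 and apoptosis, MYC, metabolism, stress and signalling responses, histones, ribosomal proteins, antigen presentation and reference genes.

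Named genes followed a rule fixed in advance. JMJD1C came first, then the 12 highest and 12 lowest genes called in 1 direction with both hairpins with a single symbol and at least 5 FPKM. The 3 highest and 3 lowest called genes of each hairpin, the 8 highest and 8 lowest called genes of the AML1-ETO table, and the 6 highest and 6 lowest genes called in all 3 tables followed, under the same filter on single symbols and FPKM where the rule gives it. Up to 4 called members per list and the members of the AML1-ETO complex completed it. Of the genes that the rule names, 2 annotated on the Y chromosome are not reported. Some other genes that the rule names, and the list of megakaryocyte genes, are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

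Coordinates are those of the tables on hg19. Locus starts in the tables count from 0, since end minus start equals the annotated gene length for 16940 of 21623 genes, so 1 was added. A locus in these tables can span several overlapping gene models, and genes that share one, near-identical copies and antisense partners are uncertain. The alternatives tried were a q of 0.01, a fold of at least 1.5, FPKM floors of 1 and 5, an adjustment recomputed over genes with at least 1 FPKM, pseudocounts of 0.1 and 5, centring on the median, the authors' log2 fold change, 1 gene per locus and symbol, and another error for the hairpin difference. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.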

Results

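Gene expression was measured by RNA sequencing in Kasumi-1 cells, a human leukemia line that carries AML1-ETO, a fusion of the transcription factor RUNX1 with RUNX1T1. JMJD1C, a JmjC-domain protein of the KDM3 family, was targeted with 2 different short hairpin RNAs, and the comparisons asked how its depletion changed the transcriptome. There were 6 libraries, 2 each for the control shRNA, JMJD1C shRNA63 and JMJD1C shRNA95, collected 4 days after infection. FPKM values are the authors' group values, 1 per group, and errors of log2 fold changes are derived from the authors' test statistic. A further table of the authors compared AML1-ETO knockdown with its control, with 1 library each from another series. The depth per library is unknown, and an estimate from genes with very low values was 0.79 times that of the controls for shRNA63 and 0.71 times for shRNA95.

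JMJD1C mRNA was lower with shRNA63, while with shRNA95 a loss was not detectable. JMJD1C (ENSG00000171988) lies on chromosome 10 from 64926981 to 65225722 in hg19, on a locus that holds 6 genes in the tables, so its value can include reads of overlapping genes. With shRNA63 the authors' group value fell from 30.4 to 13.7 FPKM, or 45.1% of control, with a log2 fold change of -1.15 (error 0.30) in the authors' deposited table (q = 0.00214). In the libraries labelled shRNA95 it stood at 25.1 against 29.4 FPKM in the authors' deposited table, or 85.3% of control. The log2 fold change there was -0.23 in the authors' deposited table (error 0.30, 95% interval -0.81 to 0.35, q = 0.938). JMJD1C mRNA therefore gives no check of the shRNA95 label, and every direction given for these libraries rests on the label alone. Between the hairpins JMJD1C differed by -0.92 on the log2 scale (error 0.42), with an unadjusted p of 0.0290 and an adjusted p of 0.691. In the AML1-ETO comparison the authors' deposited table gave JMJD1C a log2 fold change of -0.26 (error 0.56), which was not called.

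With shRNA63, myeloid granule and monocyte genes were higher, and mast cell genes and amino acid and ATF4 response genes were lower. Of 11 measured neutrophil granule genes 6 were called higher (9 adjusted over the list alone), and the list median was 0.55 on the log2 scale. AZU1, which encodes azurocidin, rose from 1040 to 2592 FPKM and CTSG, which encodes cathepsin G, from 253.9 to 454.6 FPKM in the authors' deposited table. Of 9 monocyte and macrophage genes 3 were called higher (4 adjusted over the list alone). They were LYZ, which encodes lysozyme, with a log2 fold change of 3.02 (error 0.29), the nuclear antigen gene MNDA with 2.42 (error 0.30) and the Toll-like receptor gene TLR2 with 1.75 (error 0.23) in the authors' deposited table. Of 4 mast cell, basophil and eosinophil genes 3 were called lower, the tryptase genes TPSB2 and TPSAB1 and SLC45A3 (adjusted over the list alone, 3 lower and 1 higher). PRG2, an eosinophil granule gene of that list, went the other way without a call, from 1.65 to 9.56 FPKM in the authors' deposited table. TPSB2 and TPSAB1 are near-identical copies whose reads may be split between them, so their calls, and the test of this list with either hairpin, may not count separate genes. By Fisher's exact test the adjusted p was 2.23e-06 for granule genes, 0.0165 for monocyte genes and 0.00247 for mast cell genes.

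Of 23 amino acid and ATF4 response genes 9 were called lower with shRNA63 (11 adjusted over the list alone), with a list median of -0.57 and an adjusted Fisher p of 6.28e-07. PHGDH, the first enzyme of serine synthesis, fell from 139.5 to 59.4 FPKM with a log2 fold change of -1.23 (error 0.25) in the authors' deposited table. DDIT4, an inhibitor of mTORC1 signalling, was at -1.22 (error 0.27), the pseudokinase gene TRIB3 at -1.13 (error 0.27) and CBS, an enzyme of cysteine synthesis, at -1.23 (error 0.32) in the authors' deposited table. Of 20 immediate early genes 4 were called lower (5 adjusted over the list alone, adjusted Fisher p = 0.0385). Among them DUSP6, an ERK phosphatase, fell from 77.2 to 25.1 FPKM in the authors' deposited table. Of 25 glycolysis genes 2 were called lower (3 adjusted over the list alone), with an adjusted Fisher p of 0.792, and the list median of -0.35 lay at percentile 0 of 10000 matched random lists. They were the lactate transporter gene SLC16A1, from 104.5 to 27.6 FPKM, and LDHA, from 701.3 to 445.6 FPKM in the authors' deposited table. DNA replication genes had a median of -0.41, also at percentile 0 of matched random lists, and 32 of 35 had negative ratios. Of them RFC3 and UHRF1 were called lower (7 adjusted over the list alone, and 13 at an unadjusted p under 0.05), with an adjusted Fisher p of 1. Of 10 replication-dependent histone genes 3 were called higher (3 adjusted over the list alone, adjusted Fisher p = 0.0215), among them HIST1H2AC and HIST1H2BK.

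In all, the authors' deposited table called 936 of 18271 tested genes with shRNA63, 419 higher and 517 lower, and 14 of them had a group listed at 0. Among the lowest were AP001427.1 and AC061975.7, both listed at 0 with shRNA63. The median log2 ratio of 14475 measured genes was 0.0087.

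In the libraries labelled shRNA95, granule and monocyte genes were higher, and so were genes of protein folding and of cholesterol synthesis. Of 12 measured neutrophil granule genes 9 were called higher (10 adjusted over the list alone), with a list median of 0.85. Of 9 monocyte and macrophage genes 6 were called higher (6 adjusted over the list alone), with a median of 1.85. S100A9, a calcium-binding protein of neutrophils and monocytes, rose from 89.0 to 429.3 FPKM, a log2 fold change of 2.27 (error 0.19) in the authors' deposited table. Of 28 heat shock and unfolded protein response genes 10 were called higher (11 adjusted over the list alone), and 27 had positive ratios. The list median was 0.47, against 0.12 for random lists matched on expression. HSPA5, a chaperone of the endoplasmic reticulum, rose from 194.6 to 457.5 FPKM, with a log2 fold change of 1.23 (error 0.24), and CALR, which encodes calreticulin, had 1.07 (error 0.34) in the authors' deposited table. Of 21 cholesterol biosynthesis genes 4 were called higher (9 adjusted over the list alone). All 21 had positive ratios with a median of 0.56, against 0.099 for random lists matched on expression. Among them INSIG1, a regulator of sterol synthesis, was at 0.76 (error 0.29) and DHCR7, the last enzyme of the pathway, at 0.81 (error 0.31) in the authors' deposited table. The adjusted Fisher p was 2.76e-10 for granule genes, 1.65e-06 for monocyte genes, 1.96e-07 for heat shock and unfolded protein response genes and 0.0385 for cholesterol genes.

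Mast cell genes were lower in the libraries labelled shRNA95 too, with TPSB2, TPSAB1 and SLC45A3 called among 5 measured genes (adjusted over the list alone, 3 lower and 2 higher; adjusted Fisher p = 0.00154). Of 7 stem and progenitor genes 1 was called higher and 2 lower (1 and 3 adjusted over the list alone), with an adjusted Fisher p of 0.0752 for lower calls. CD34, a surface marker of progenitors, rose from 146.1 to 249 FPKM, while MSI2, an RNA-binding protein, fell from 43.3 to 14.3 FPKM and the surface protein gene CD200 from 9.39 to 3.69 FPKM in the authors' deposited table. Of 14 reference genes HPRT1 was called lower, from 87.9 to 37.8 FPKM in the authors' deposited table, and the list alone gave 1 higher and 1 lower. The authors' deposited table called 793 of 18006 tested genes, 466 higher and 327 lower, and 14 of them had a group listed at 0. TRGJP1, MIR4458 and RNU4-1 led the higher genes and were listed at 0 in the control, and RNA5SP284 was listed at 0 with shRNA95. TRGJP1 and MIR4458 were also listed at 170.9 and 65.2 FPKM with shRNA63 against 0 in the control, without a call. These loci are very short (38315860 to 38315919 on chromosome 7 for TRGJP1), so scaling to length makes their FPKM uncertain. The median log2 ratio of 14391 measured genes was 0.032.

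**Figure D1:**
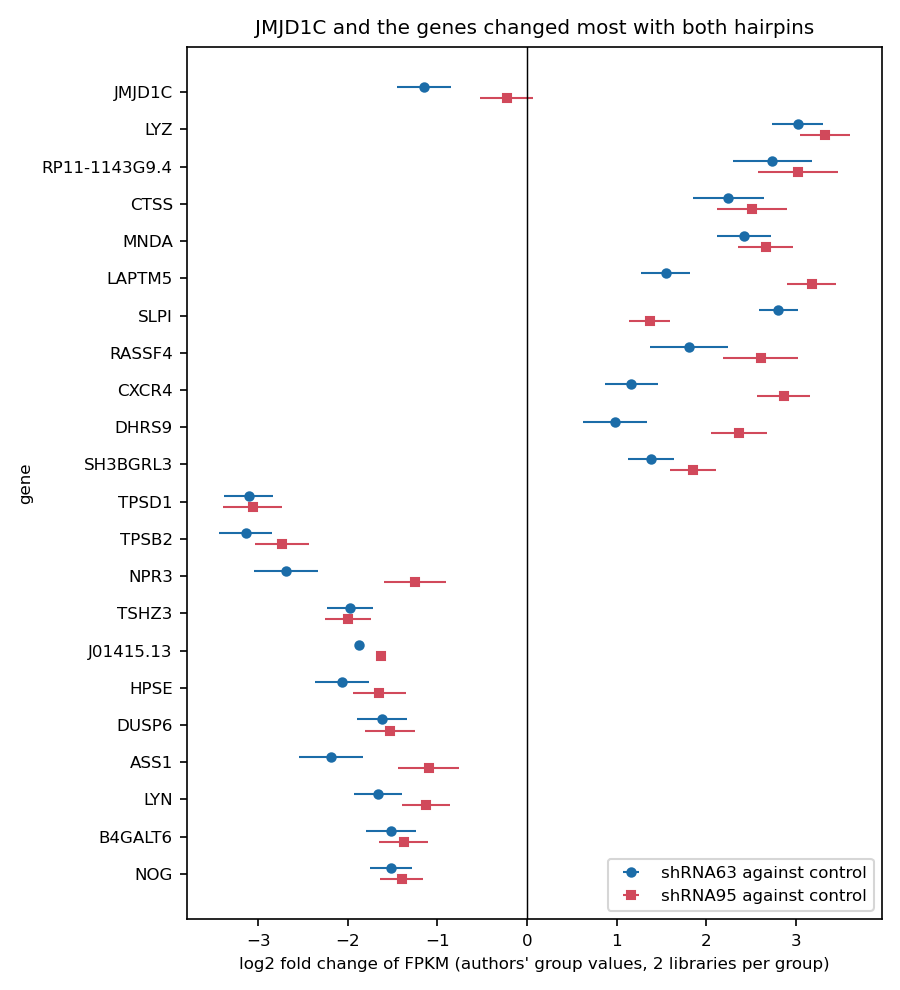
Log2 fold change of FPKM against the control shRNA for JMJD1C and the highest and lowest genes called in the same direction with both hairpins, for shRNA63 (circles) and shRNA95 (squares), from the authors' deposited tables, with bars of 1 error derived from the authors' statistic (those of J01415.13 are smaller than its symbols). LYZ stands at 3.02 and 3.32 and TPSD1 at -3.11 and -3.06, while JMJD1C stands at -1.15 and -0.23.

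Both hairpins changed 239 genes in the same direction, 126 higher and 113 lower, the shRNA95 direction resting on the label of its libraries. The highest included LYZ, the protease gene CTSS, MNDA, LAPTM5 (a lysosomal membrane protein of blood cells), the protease inhibitor gene SLPI, RASSF4, the chemokine receptor gene CXCR4, DHRS9 and SH3BGRL3. CTSS rose from 5.82 to 27.6 FPKM with shRNA63 and from 5.64 to 32.0 FPKM with shRNA95 in the authors' deposited tables. RP11-1143G9.4 was also among the highest but shares its locus with LYZ and is uncertain. The lowest included the tryptase genes TPSD1 and TPSB2, which are near-identical copies and therefore uncertain, the natriuretic peptide receptor gene NPR3, TSHZ3, the mitochondrial transcript J01415.13, HPSE (heparanase), DUSP6, ASS1, the tyrosine kinase gene LYN, B4GALT6 and NOG, which encodes a BMP antagonist. J01415.13 spans only 7518 to 7585 of the mitochondrial genome, so its FPKM and its very small error are uncertain. HPSE fell from 29.8 to 7.11 FPKM and from 28.9 to 9.23 FPKM, and LYN from 87.9 to 27.7 FPKM and from 85.2 to 39.0 FPKM in the authors' deposited tables. Among blood transcription factor genes, SPI1, which encodes PU.1, was called higher with both hairpins and ERG lower with both, and GATA2 was called lower with shRNA95. That list of 15 measured genes had 1 call in each direction with shRNA63 (2 and 2 adjusted over the list alone), and 1 higher and 2 lower with shRNA95 (1 and 2 adjusted over the list alone). RUNX1, RUNX1T1, CBFB, TCF3, TCF12, LYL1, LMO2 and LDB1, which encode members of the AML1-ETO complex, were not called with either hairpin. The list that holds them and the blood transcription factors still had a median of -0.19 with shRNA95, with 13 of 15 ratios negative. That median lay at percentile 0.08 of matched random lists. With shRNA63 the median was 0.12, at percentile 92.04, with 9 of 15 positive.

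Independent lists of these sizes would share 10.1 higher and 9.63 lower genes among 17493 genes tested in both tables. Unchanged groups simulated against the shared controls gave 1.03 higher and 0.91 lower shared calls among 13870 genes, where 116 and 96 were observed. The simulated counts follow from the cut on p and from equal shares of error for control and shRNA groups. They also take the deposited p-values as exact, so they cannot say how many shared calls came from the control libraries. Across 14014 genes, which are not independent replicates, the log2 ratios of the hairpins had a Pearson correlation of 0.49 and a Spearman correlation of 0.37. Their covariance was 0.143. Genes with a group listed at 0 are included there but have no error, such as MIR4458, with ratios of 6.05 and 7.42 against a control at 0. Over the 13870 genes with an error in both tables the hairpin ratios had a Pearson correlation of 0.41 and a covariance of 0.0724. Simulation over those genes gave a correlation of 0.50 and a covariance of 0.640 with errors from the statistic or 0.319 with errors from p. The difference in covariance, -0.567 or -0.247, gives no estimate of a shared effect. For 10521 genes with errors under 0.5 once scaled to the deposited p, a limit set after that result had been seen, the observed covariance was 0.0647 against 0.0559 or 0.0277 simulated, while the observed correlation was 0.41 against 0.50 simulated with either error. The simulation gave the control and shRNA groups equal shares of the error, which sets its correlation near 0.50 whatever the size of the errors. The comparison of correlations therefore cannot decide how much of the observed one came from shared controls. The 2 control libraries could not be split, and some of the shared calls may come from them too.

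The hairpins also differed from each other. TM4SF1, a membrane protein gene, had log2 fold changes of 1.11 (error 0.30) with shRNA63 and -2.83 (error 0.40) in the libraries labelled shRNA95 in the authors' deposited tables, a difference of 3.94. INSIG1 was called lower with shRNA63, at -1.15 (error 0.29), and higher with shRNA95, at 0.76 (error 0.29), in the authors' deposited tables. The granule gene BPI differed by -3.00 (error 0.60) and S100A9 by -1.81 (error 0.36). The test of the difference, with Benjamini-Hochberg adjustment, passed for 150 of 13870 genes, of which 49 were higher and 101 lower with shRNA63 than with shRNA95. With the shared control part of the errors removed, 587 genes passed. Calls in opposite directions were made for 20 genes, 6 higher with shRNA63 against 7.40 expected from independent lists and 14 lower against 13.1. Noise in the shared controls moves both comparisons alike, so independent lists may overstate the opposite calls expected. Among those 14, AIF1 (-1.65 and 0.79), S100P (-2.17 and 1.24) and MMP25 (-2.28 and 0.96) were named after their values were seen. The list median of shRNA63 minus shRNA95 was -0.88 for amino acid and ATF4 response genes, -0.74 for cholesterol genes, -0.44 for heat shock and unfolded protein response genes and -1.19 for monocyte genes. Each of these 4 medians lay at percentile 0 of 10000 random lists matched on expression, and so did those of fatty acid synthesis (-0.56), immediate early (-0.45), glycolysis (-0.41) and DNA replication genes (-0.35). Genes known as repressed by AML1-ETO were at -0.46 (percentile 0.04), while AML1-ETO complex and blood transcription factor genes went the other way, at 0.25 (percentile 99.96), with 12 of 15 positive. Members of a list can move together, so these percentiles do not measure spread between cultures.

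**Figure D2:**
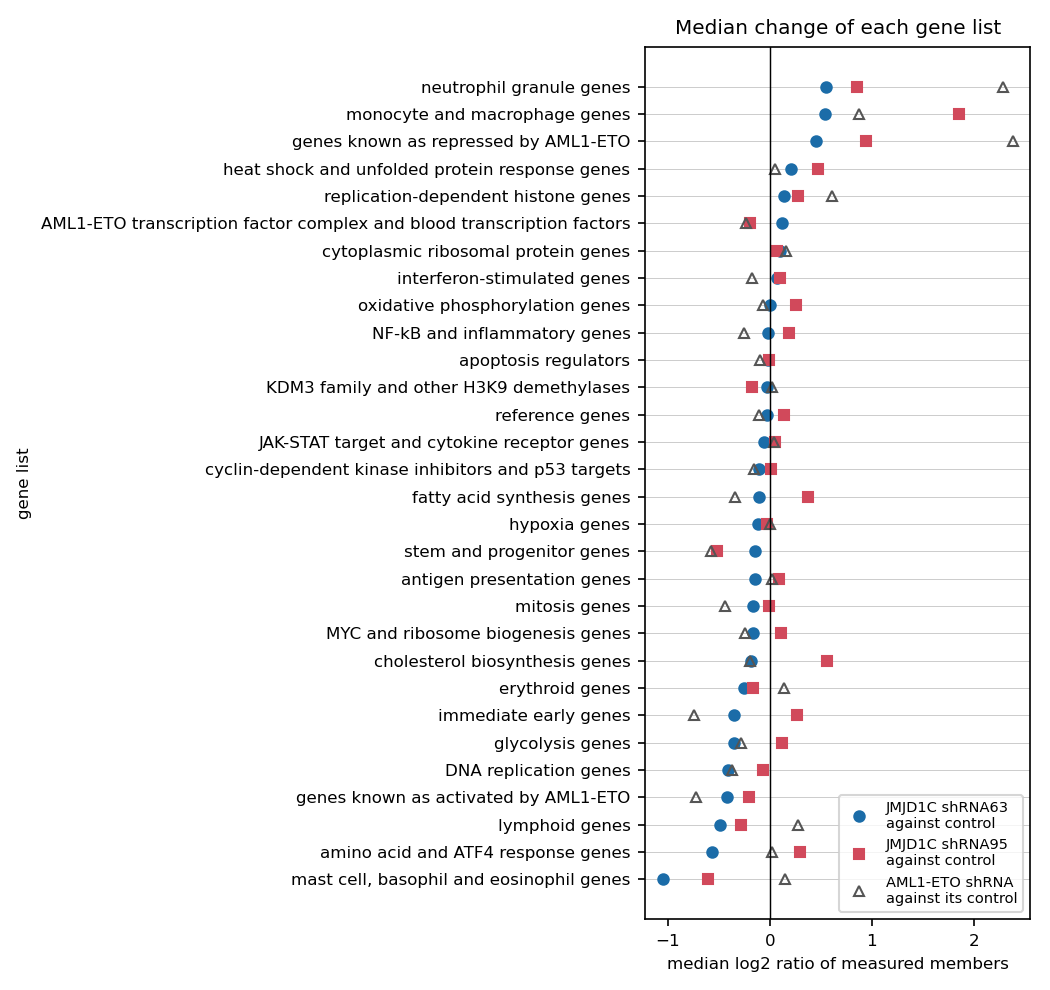
Median log2 ratio of the measured members of each gene list reported here for shRNA63, shRNA95 and, as the authors' log2 fold change and without a filter on level, the AML1-ETO comparison. Neutrophil granule genes stand at 0.55 and 0.85 with the hairpins and 2.29 in the authors' deposited table for AML1-ETO, and amino acid and ATF4 response genes at -0.57, 0.30 and 0.02.

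In the AML1-ETO comparison granule and other myeloid genes were among the highest called genes with at least 5 FPKM in a JMJD1C table. That filter favours genes that rose with a hairpin. BPI and S100A8 passed it with 27.1 and 52.7 FPKM in the shRNA95 group, against 2.05 and 0.0818 FPKM in the control. CST7 at 5.56 and IL6R at 4.06, also called higher in the authors' deposited table, fell below it. The authors' deposited table gave log2 fold changes of 6.23 (error 0.62) for BPI, 6.21 (error 0.72) for PRG2, an eosinophil granule protein gene, 4.82 (error 0.56) for LAPTM5 and 4.31 (error 0.82) for the tetraspanin gene CD82. S100A8, ANXA1, RASGRP2 and CTSG followed, from 4.25 down to 3.33 in the authors' deposited table. The lowest were TM4SF1 at -6.03 (error 0.87), the VEGF receptor gene FLT1 at -5.35 (error 0.84), DUSP27 at -5.13 (error 0.79) and PADI3 at -4.79 (error 0.70) in the authors' deposited table, followed by ADAM28, PTRF, HPSE and TTC29. RUNX1T1, one partner of the fusion, stood at -1.04 (error 0.87) in the authors' deposited table and was not called. The gene lists had no filter on level in this table, so more members could enter than with the hairpins. Of 13 neutrophil granule genes 6 were called higher in the authors' deposited table (10 adjusted over the list alone), and their median of 2.29 lay at percentile 100 of 10000 matched random lists. Of 17 monocyte genes 1 was called higher in the authors' deposited table (1 adjusted over the list alone), with a median of 0.88. CD34 was called lower at -2.15 (error 0.53) in the authors' deposited table, and it was the 1 call among 13 stem and progenitor genes (1 adjusted over the list alone). The authors' deposited table called 92 of 22406 tested genes, 50 higher and 42 lower, and 11 of them had a group listed at 0. This comparison has no replicate check, and its test compares 2 libraries, not the conditions.

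Genes called with both JMJD1C hairpins had the same direction in the AML1-ETO comparison more often than all measured genes. LAPTM5, SLA, CTSG, SPI1 and RP11-800A3.4 were called higher in all 3 tables, and HPSE, PADI3, FLT1, ADAM28, TSHZ3 and PTRF lower in all 3. SPI1 had log2 fold changes of 0.72 (error 0.25) with shRNA63, 1.63 (error 0.26) in the libraries labelled shRNA95 and 2.17 (error 0.52) with AML1-ETO knockdown in the authors' deposited tables. FLT1 had -0.88 (error 0.29), -1.31 (error 0.28) and -5.35 (error 0.84) in the authors' deposited tables. Among 16938 genes tested in all 3 of the authors' deposited tables, 14 were called higher in all against 0.275 expected from independent lists, and 17 lower against 0.240. None of the genes called in 1 direction with both hairpins was called in the opposite direction in the authors' deposited table for AML1-ETO. Independent lists would give only 0.268 and 0.247 such genes, so their absence carries little weight. For shRNA63 alone, 15 higher and 19 lower genes matched in direction in the authors' deposited tables. TM4SF1 was called higher with shRNA63 and lower with AML1-ETO shRNA in the authors' deposited tables, and 3 genes the reverse. For shRNA95 alone, 26 higher and 30 lower genes matched, and 1, CD34, was higher there and lower in the authors' deposited table for AML1-ETO. Of 116 measured genes called higher with both hairpins, 102 were positive in the authors' deposited table for AML1-ETO, or 87.9% (exact 95% interval 80.6 to 93.2%), against 44.1% of all measured genes. Of 96 called lower, 94 were negative in the authors' deposited table, or 97.9% (92.7 to 99.7%), against 55.9% of all measured genes. These intervals treat genes as independent. Across 13579 genes, which are not independent replicates, Pearson and Spearman correlations with the authors' deposited table for AML1-ETO were 0.31 and 0.35 for shRNA63, 0.39 and 0.41 for shRNA95, and 0.42 and 0.45 for their mean.

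**Figure D3:**
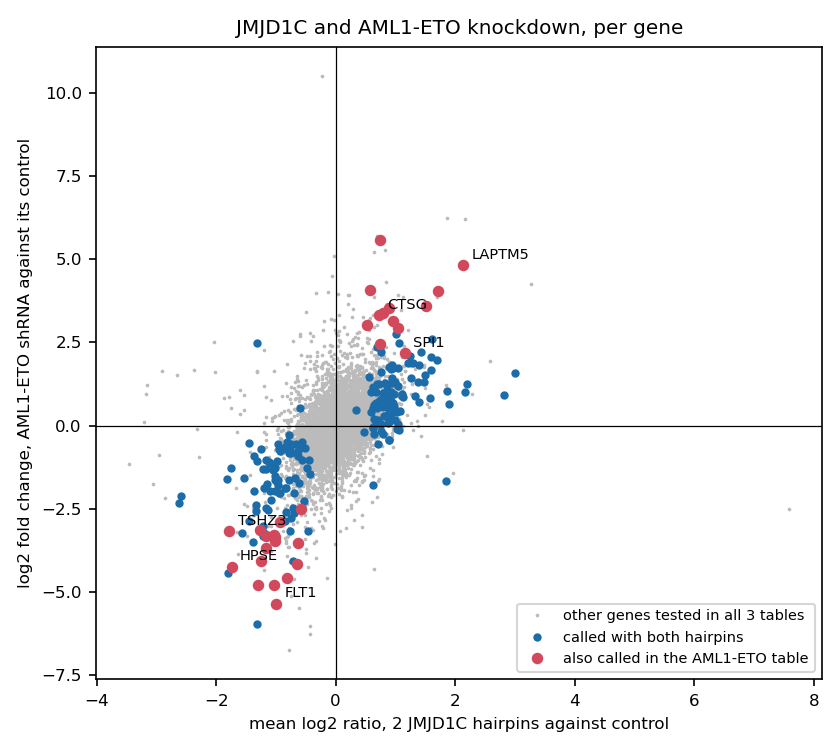
Log2 fold change with AML1-ETO shRNA in the authors' deposited table against the mean log2 ratio of the JMJD1C hairpins, for 13134 genes tested in all 3 tables with a single entry for their symbol, at least 1 FPKM in a JMJD1C table, a finite log2 fold change with an error in the authors' deposited table for AML1-ETO, and no place on the Y chromosome. Of the 214 of these genes called with both hairpins (blue or red), the 13 higher and 17 lower genes also called with AML1-ETO shRNA in the authors' deposited table (red) lie in the upper right and lower left quadrants.

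Genes known as repressed by AML1-ETO had more higher calls than other measured genes with each hairpin. With shRNA63, 4 of 12 were called higher and 2 lower (6 and 2 adjusted over the list alone), and in the libraries labelled shRNA95 8 of 14 higher and 1 lower (8 and 1 adjusted over the list alone). The adjusted Fisher p for higher calls was 0.00272 and 8.68e-08. LAPTM5, SPI1 and CTSG were higher with both hairpins, and CD48, a surface protein of leukocytes, was lower with both. In the AML1-ETO comparison 8 of 16 were called higher in the authors' deposited table (9 higher and 1 lower adjusted over the list alone), with a median of 2.38. Of 13 genes known as activated by AML1-ETO, 3 were called lower with shRNA63 (5 adjusted over the list alone, adjusted Fisher p = 0.0752). With shRNA95, 3 were called lower and 1 higher (4 and 1 adjusted over the list alone, adjusted Fisher p = 0.0235 for lower calls). EGR1 and ID1, which encode transcriptional regulators, were lower with both hairpins, the phosphatase gene UBASH3B with shRNA63, and TRH, which encodes a peptide hormone, with shRNA95. In the AML1-ETO comparison 1 of 15 was called lower in the authors' deposited table (1 adjusted over the list alone), with a median of -0.73.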

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

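All tests of explanations in this part were chosen after the results were seen, while the test of the difference between hairpins was planned.

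A difference between the hairpins, by the test of the difference itself with Benjamini-Hochberg adjustment, singled out 17 named genes. Values are the log2 fold change with shRNA63 minus that in the libraries labelled shRNA95, computed from the authors' deposited tables. ANXA1 stood at -3.30 (error 0.67), BPI at -3.00 (error 0.60) and KLF2 at -2.54 (error 0.53). The difference was -1.93 for SLC16A1, -1.91 for TTC29, -1.90 for INSIG1, -1.81 for S100A9, -1.70 for CXCR4, -1.65 for RRM2B, -1.63 for LAPTM5, -1.38 for EGR1 and -1.37 for PHGDH. Genes higher with shRNA63 than with shRNA95 were TM4SF1 at 3.94 (error 0.50), CDKN1C at 1.85, MYCN at 1.81, TRH at 1.44 and SLPI at 1.44. Among these 17 the highest adjusted p was 0.0349, for EGR1.

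The first pattern weighed was that amino acid and ATF4 response genes were lower with shRNA63 and not in the libraries labelled shRNA95. A scaling difference between the groups of the shRNA63 table would move all lists alike and is argued against by the list median, which lay -0.572 from the median of matched random lists of that table, at percentile 0 of 10000. Values near the floor are argued against by the 13 members with at least 20 FPKM, whose median was -0.595 (quartiles -1.03 and -0.363). A response in proportion to the loss of JMJD1C mRNA would lower the list with shRNA95 only if that mRNA fell there. The JMJD1C interval with shRNA95, -0.81 to 0.35, holds 0. The list median with shRNA95 was 0.30, at percentile 99.75 of matched random lists, so it was not lower there. The rule written for this test counted that against the explanation, but it took a loss of the mRNA with shRNA95 as given. Since that loss was not detectable, the list median cannot decide this, and the explanation stays open. A target of 1 hairpin other than JMJD1C could account for the list difference of -0.880 and stays open, since the tables hold no rescue and no further hairpin.

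The second pattern was the set of genes called in the same direction with both hairpins. Gene-by-gene noise in the shared control libraries is argued against by the 87.9% of genes called higher with both that were positive in the authors' deposited table for AML1-ETO, which has other controls, against 44.1% of all measured genes. Control cultures that were less mature as a whole could also give the higher granule genes, whose median was 0.551 with shRNA63. This cannot be told apart from an effect of JMJD1C loss, because both hairpins were compared with the same 2 control libraries.

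The third pattern was that JMJD1C mRNA was not called lower in the libraries labelled shRNA95. Control libraries under that label stay open: the 793 called genes do not exclude a separate control culture, since the tables hold no comparison of controls with each other, and the JMJD1C interval there, -0.81 to 0.35, holds 0. An earlier reading of that count had argued against this explanation and was set aside after its result had been seen. Too little precision stays open: the hairpins differed at JMJD1C by -0.921, with an unadjusted p of 0.0290 and an adjusted p of 0.691. The interval with shRNA95 still leaves room for a partial loss, down to -0.81. The adjustment was over 13870 genes although JMJD1C was named in advance, and independent errors are too wide here. The test of the difference was therefore conservative for this gene. This test replaced an earlier one, set aside after its result had been seen, which asked whether the shRNA95 interval held the shRNA63 value, left out the shRNA63 error and had argued against this explanation. A loss of JMJD1C protein without loss of the mRNA, at -0.229 in the authors' deposited table, could not be examined in RNA of 1 time point and stays open.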

How the results depend on the processing

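The settings "alone on their locus" and "errors scaled to the deposited p" were chosen after the data were seen, and the others were planned. With a q of 0.01 the counts of called genes were 559 for shRNA63, 508 for shRNA95, 145 for both hairpins, and 0 for AML1-ETO and 0 for the overlap with it from the authors' deposited table. Those 0 counts follow from the smallest q of 0.0178 from Cuffdiff in the authors' deposited table, where 1494 genes had an unadjusted p under 0.05. With at least 5 FPKM the counts were 599 for shRNA63, 152 for both hairpins, 45 for AML1-ETO and 20 for the overlap, and the share called higher was 40% for AML1-ETO against 54.3%, and 30% for the overlap against 45.2%, from the authors' deposited table. Genes alone on their locus numbered 459, 422, 49 and 119 for shRNA63, shRNA95, AML1-ETO and both hairpins in the authors' deposited tables. These counts fell because fewer genes entered. The hairpin difference passed for 587 genes with the shared control part removed and for 591 with errors scaled to the deposited p. Correlations of the hairpins, of shRNA63 with AML1-ETO and of shRNA95 with AML1-ETO were 0.548, 0.284 and 0.370 with a pseudocount of 0.1 and 0.453, 0.348 and 0.427 with the log2 fold changes of the authors' deposited tables. The hairpin correlation was 0.451 with a pseudocount of 5 and 0.506 with at least 5 FPKM, and that of shRNA95 with the authors' deposited table for AML1-ETO 0.368 and 0.413. The cause was not tested. The balance of calls turned from mostly higher to mostly lower for both hairpins with a q of 0.01 (68 higher and 77 lower), and for AML1-ETO with at least 5 FPKM (18 and 27) and with the recomputed adjustment (36 and 38) in the authors' deposited table. No correlation changed sign. Of the list medians under the alternatives 346 kept their side of the limits set by random lists, 5 moved beyond them and 15 moved within them. No paired analysis was possible because the tables hold no value per library. For the same reason leaving out a replicate, the replicate number as a block and DESeq2 were not run, and depth could not be tested as a limit.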

Other observations

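No test in this part was chosen after the results were seen, as the gene lists and their counts were planned.

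Stress, lipid and metabolic genes had these further calls. With shRNA63, 2 of 28 heat shock and unfolded protein response genes were called higher and 1 lower (3 and 1 adjusted over the list alone), HSPA5 among the higher, and 2 of 21 cholesterol genes, INSIG1 and HMGCS1, were called lower (2 adjusted over the list alone). In the libraries labelled shRNA95, Cuffdiff called 0 of 23 amino acid and ATF4 response genes (0 adjusted over the list alone), with 9 higher and 1 lower at an unadjusted p under 0.05. Immediate early genes had 3 higher and 2 lower calls of 21 with shRNA95 (6 and 2 adjusted over the list alone), KLF2 and ATF3 among the higher. Of 25 glycolysis genes GPI was called higher with shRNA95 (1 adjusted over the list alone). Cuffdiff called 0 of 35 DNA replication genes and 0 of 12 histone genes with shRNA95, with 1 higher and 2 lower, and 1 lower, at an unadjusted p under 0.05.

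Cell cycle and survival genes had few calls. Of 35 mitosis genes TOP2A, the topoisomerase of dividing cells, was called lower with shRNA63 (1 adjusted over the list alone). Cuffdiff called 0 of them with shRNA95, with 0 at an unadjusted p under 0.05, and their median in the authors' deposited table for AML1-ETO was -0.44 with 34 of 35 negative. Among 20 cyclin-dependent kinase inhibitors and p53 targets, RRM2B was called lower with shRNA63 (3 adjusted over the list alone), and with shRNA95 CDKN2D and BBC3 were higher and CDKN1C lower (2 and 2 adjusted over the list alone). Of 22 apoptosis regulators Cuffdiff called 0 with shRNA63, with 2 lower at an unadjusted p under 0.05. With shRNA95, BBC3 and PMAIP1 were higher and BCL2L1, an inhibitor of apoptosis, lower (2 and 1 adjusted over the list alone). Of 33 measured entries for MYC and ribosome biogenesis genes, 2 of them for PA2G4, POLR1B was called lower with shRNA63 and MYCN lower with shRNA95 (1 each adjusted over the list alone).

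Inflammatory and signalling genes went both ways. Of 12 NF-kB and inflammatory genes IL8 and TNFAIP3 were called higher and IL1B lower with shRNA63 (2 and 1 adjusted over the list alone), and 1 was higher and 2 lower with shRNA95 (1 and 2 adjusted over the list alone), IL8 again higher. Of 28 interferon-stimulated genes IFI35 and HERC5 were higher and OASL lower with shRNA63 (6 and 4 adjusted over the list alone), and IFI35 and ISG15 higher with shRNA95 (3 higher and 1 lower adjusted over the list alone). The hypoxia gene NDRG1, 1 of 15, was higher with shRNA63 (1 adjusted over the list alone), and Cuffdiff called 0 of 15 with shRNA95, with 1 higher and 2 lower at an unadjusted p under 0.05. Of 16 JAK-STAT target and cytokine receptor genes IL2RG was lower with shRNA63 and IL6R higher with shRNA95 (1 each adjusted over the list alone). Called members under 1 FPKM are left out of the counts in this part, and IL6R was 1 of them with shRNA63, where it was also called higher, with a log2 fold change of 1.49 (error 0.94) in the authors' deposited table. Of 15 fatty acid synthesis genes ME1 was higher with shRNA63 (1 higher and 1 lower adjusted over the list alone) and ELOVL1 with shRNA95 (1 adjusted over the list alone). Antigen presentation genes had 2 lower calls of 12 with shRNA63, NLRC5 among them (2 lower and 1 higher adjusted over the list alone), and 1 higher of 13 with shRNA95 (1 adjusted over the list alone).

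Among lineage lists, CD79A of 5 lymphoid genes was lower with shRNA63 (2 adjusted over the list alone), and NKG7 of 4 was higher with shRNA95 (1 higher and 1 lower adjusted over the list alone). Of 2 erythroid genes KLF1 was lower with shRNA95 (1 adjusted over the list alone). Cuffdiff called 0 with shRNA63 (1 lower adjusted over the list alone), with 1 lower at an unadjusted p under 0.05. Of 8 stem and progenitor genes KIT was lower with shRNA63 (2 adjusted over the list alone). Of 10 H3K9 demethylase genes JMJD1C was the 1 called with shRNA63 (1 adjusted over the list alone), and Cuffdiff called 0 with shRNA95, with 1 lower at an unadjusted p under 0.05. Cuffdiff called 0 of 33 entries for 32 oxidative phosphorylation genes, NDUFB8 having 2 entries, with either hairpin, with 1 lower for shRNA63 and 7 higher for shRNA95 at an unadjusted p under 0.05. It called 0 of 42 ribosomal protein genes with either hairpin, with 0 at an unadjusted p under 0.05, and 0 of 14 reference genes with shRNA63, with 1 higher and 1 lower at an unadjusted p under 0.05.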
